A study of Mus musculus with 19 samples.

How the data were processed

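The series holds 16 RNA libraries and 3 chromatin immunoprecipitation libraries from mouse Th2 cells. Per the labels, RNA was purified with RNeasy, 10 ng was amplified with NuGEN Ovation V2, and libraries were sequenced on a HiSeq instrument. Each RNA table gives, per RefSeq transcript, raw read counts, RPKM, a transcript length and a gene symbol. The counts are the authors' deposited reads per transcript, without normalization. The RPKM values are the authors' deposited reads scaled to transcript length in kilobases and to a library total. The submitters' processing notes name CASAVA 2.18, TopHat2 2.0.13, Bowtie, Novoalign, MACS 1.4.2 and mm10 without saying which tool served which assay. The counting tool, the strand used and the treatment of reads that map to several places are not given in the sources used here. Each table has 29257 transcripts of 22878 gene symbols. For each gene the transcript with the most reads over all 16 libraries was used, because transcripts of a gene share reads.

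Counts were tested, since raw counts were deposited. The deposited RPKM values served the filter on low values and an alternative test. Genes with an RPKM of at least 1 in at least 2 of the 8 libraries of an experiment were kept, which left 10873 genes in the Bcl11b experiment and 10601 in the Gata3 experiment. Each experiment had its own fit of 8 libraries in 4 groups with edgeR 4.0.16 (TMM scaling and the quasi-likelihood F test). The tests were KO against WT at each stage, the difference of these effects between stages, and late against early WT. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels in CPM are TMM-scaled. Other tests of the same data used DESeq2 1.42.0, and limma 3.58.1 on log2(RPKM + 1) or log2(RPKM + 0.1). R was 4.3.3 and Python 3.11.15, with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The same code was run on simulated counts with 200 genes changed.

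The comparisons, the filter, the gene lists and the alternatives were chosen before the data were examined. Background-subtracted counts, the longest transcript per gene, genes with a read in every late library, and bound genes among the calls of a fit of only 4 libraries were added after the values were seen. Background subtraction took the rate of reads per kb over sensory receptor transcripts, times the transcript length, from every count of a library. Each group has only 2 libraries. The libraries share replicate numbers between groups, but the labels do not say that a number marks a shared animal, culture or day, so the tests are unpaired.

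The named genes follow a rule fixed in advance. For each KO comparison it names Bcl11b, Gata3, Il4, Il5, Il13, Ifng, Tbx21 and Gzmb. It adds the 10 largest rises and 10 largest falls among called genes with a mean RPKM of at least 5 in the higher group and both KO libraries on the same side of both WT libraries, without unnamed gene models and antigen receptor segments. Up to 4 called members with the smallest p-values were added per gene list. Late against early WT names the 6 largest changes in each direction, or the 5 smallest p-values where none was called. Stage differences name the 6 smallest p-values, and effects shared between experiments the 6 largest per direction by the smaller absolute log2 fold change. Named genes come from this rule, and not all of them appear in the text. Some of them are not reported here. Where a group had no read, the fold is given against a floor of 3 counts over the group. Where it had 1 to 3 reads, the ratio has an exact 95% counting interval.

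The gene lists were Th2, Th1, Th17, Treg, Tfh, cytotoxic and NK receptor, CD8 lineage, naive and memory T cell, T cell receptor and identity, IL-2 and IL-4 receptor signalling, p53 target, cell cycle, interferon response, glycolysis and hypoxia, and ILC2 genes, and markers of B cells, macrophages and dendritic cells, antigen presentation, mast cells and basophils, and erythroid cells and neutrophils. They were tested with camera from limma with a fixed correlation, with p-values adjusted over the lists of a comparison. Camera with an estimated correlation and fry served as alternatives.

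Per the file headers, each peak list gives coordinates, reads per peak, a fold enrichment, a score of -10 log10 p and, for the antibodies, an FDR in percent. The fold enrichment is the authors' ratio of a peak to its background, deposited per peak. The score and the FDR in percent are the authors' deposited values from the peak caller. They describe or rank peaks within a list only. The control and settings used in peak calling are not given in the sources used here. Of 17459 Bcl11b peaks 2197 (12.6%), and of 28612 GATA3 peaks 1413 (4.94%), overlapped 1 of the 9912 input peaks and were left out. Each peak belongs to the gene whose transcription start the authors' lists give as closest. The gene intervals quoted come from a RefSeq gene reference. The position of a peak relative to a gene comes from the gene coordinates in the peak lists. Of 27508 pairs of a GATA3 peak and its gene that were compared, 76.7% matched the reference at the gene's start or end. Overlap needed at least 1 bp, and random overlap was measured by shifting the GATA3 peaks along their chromosomes 100 times. Called and uncalled genes were compared for an assigned peak by Fisher's exact test and by logistic regression on expression and gene length.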

Results

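T helper 2 (Th2) cells are CD4 T cells that secrete interleukins 4, 5 and 13. RNA was sequenced from mouse Th2 cultures in 2 experiments, in which the transcription factor genes Bcl11b or Gata3 had been deleted. Bcl11b is a zinc-finger factor required for T cell commitment, and Gata3 is the factor that directs Th2 differentiation. In the Bcl11b experiment, cells carried a floxed Bcl11b gene and a Cre recombinase that 4-hydroxytamoxifen activates. The early cultures received 4 days of Th2 conditions. The late cultures received 4 days of Th2 conditions, 1 day of rest in IL-2 and 4 further days of Th2 conditions. The knockout (KO) cultures had 4-hydroxytamoxifen and the wild-type (WT) cultures did not, so the drug and the deletion cannot be separated. The culture of the Gata3 experiment is not given in the sources used here. Each experiment had early and late stages, WT and KO, with 2 libraries in each of 4 groups. Genomic binding of Bcl11b and GATA3 was measured in late WT Th2 cells, with 1 chromatin immunoprecipitation library per antibody and 1 input library.

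Gene reads per library ranged from 4687552 to 14577958 in the Bcl11b experiment and from 5117526 to 9892746 in the Gata3 experiment. Levels are given as mean ± SD read counts scaled to library size (CPM) over the 2 libraries of a group, and changes as log2 fold changes ± SE. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested unless another test is named, and a gene is called at an adjusted p under 0.05. Whether replicates came from separate cultures or animals is not stated, so p-values measure the spread between these samples. Intervals and floors on read counts cover counting error only. The biological coefficient of variation was 0.281 in the Bcl11b experiment and 0.125 in the Gata3 experiment. In simulated data for the early Bcl11b comparison, 25% of genes changed 2-fold and 73% of those changed 4-fold were recovered. The early Gata3 simulation gave 84% and 99%. Both simulations changed only genes above a set abundance, so recovery of genes with few reads was not measured. They gave all groups the same starting levels, without the extra background of any single group.

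The early WT libraries of the Bcl11b experiment stood apart from the other 14 libraries. Gene reads made up 20.7% of the total implied by the deposited RPKM values in replicate 1 and 16.9% in replicate 2. These libraries also had 3.73 and 4.82 reads per kb over 1472 transcripts of odorant and vomeronasal receptors, genes of sensory neurons. All other RNA libraries had at most 0.502 reads per kb over the same transcripts.

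**Figure D1:**
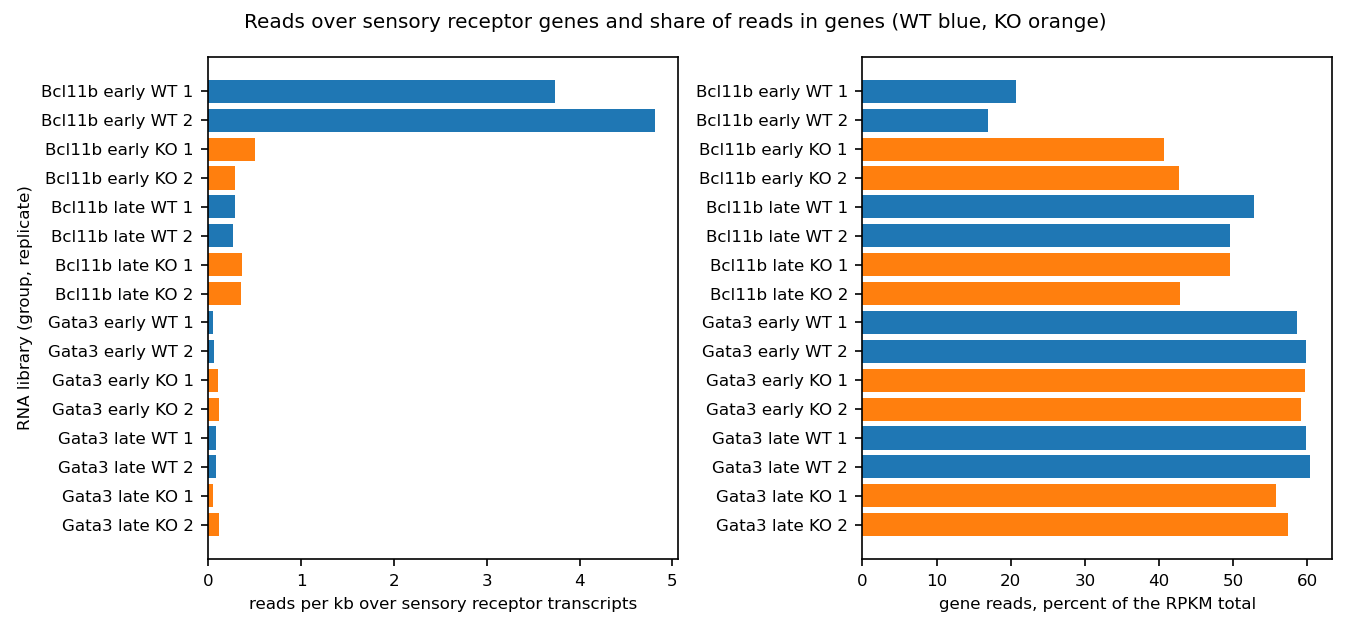
Reads per kb over odorant and vomeronasal receptor transcripts (left) and gene reads as a percent of the total implied by the RPKM values (right) in each of the 16 RNA libraries, WT in blue and KO in orange. The early Bcl11b WT libraries have 3.73 and 4.82 reads per kb and 20.7% and 16.9% of reads in genes.

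The targeted genes kept part of their reads in the KO libraries. Bcl11b (transcript NM_001079883) was at 126 and 128 CPM in the early WT libraries of its experiment and at 66.5 and 54.1 CPM in the early KO libraries, a fall of -1.08 ± 0.28 (adjusted p = 0.0234). In the late cultures Bcl11b was at 139.7 and 181 CPM in WT and at 75.6 and 137 CPM in KO, a difference of -0.59 ± 0.28 that was not called (adjusted p = 0.423). The early Bcl11b call was lost without early KO replicate 2 (adjusted p = 0.0840) or early WT replicate 1 (adjusted p = 0.0525), and its value was 0.05 and 0.06 in limma on log2(RPKM + 1) and log2(RPKM + 0.1), settings that moved the median of all genes by 0.86 and 1.14. Gata3 (NM_008091) was at 1178 and 1279.5 CPM in the early WT libraries of its experiment and at 425 and 419 CPM in early KO, a fall of -1.54 ± 0.11 (adjusted p = 3.27e-06). In late cultures Gata3 was at 1382 and 1327 CPM in WT and at 1090.4 and 954 CPM in KO, a fall of -0.41 ± 0.11 (adjusted p = 0.0319). This late Gata3 call was lost without early KO replicate 1 or 2 (adjusted p = 0.0661 and 0.0683), late KO replicate 2 (0.128), or late WT replicate 1 or 2 (0.144 and 0.105). Which exons were deleted is not given in the sources used here, and reads outside the deleted part do not check a deletion.

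**Figure D2:**
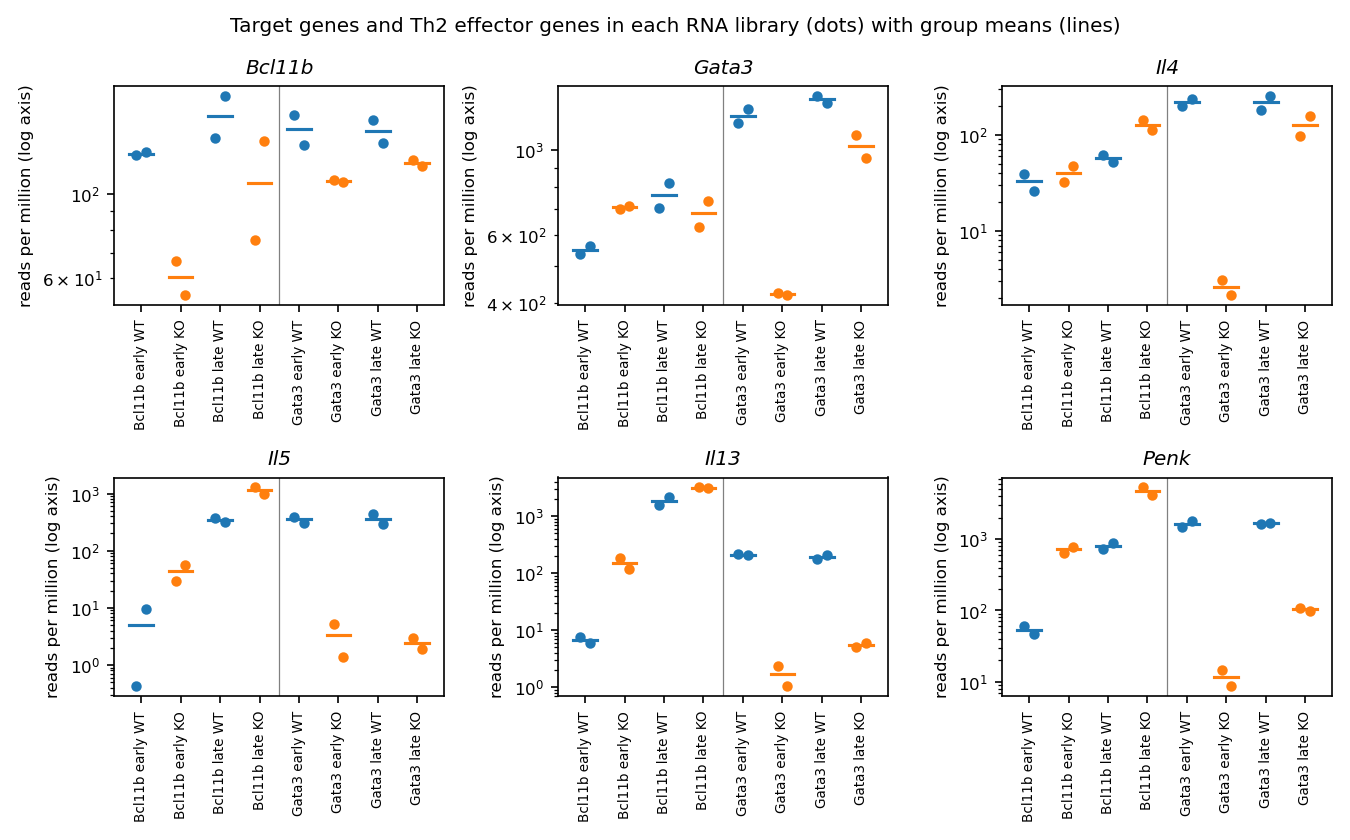
Levels of Bcl11b, Gata3, Il4, Il5, Il13 and Penk in CPM on log axes, with 1 dot per library and a line at each group mean. Il13 stands at 6.70 CPM in early WT and 150.3 CPM in early KO of the Bcl11b experiment, and at 212 CPM in early WT and 1.71 CPM in early KO of the Gata3 experiment.

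Early Bcl11b-deficient cultures were compared with WT to ask which genes depend on Bcl11b during Th2 differentiation. Cytokine genes of the Th2 programme were higher in the KO: Il13 rose from 6.70 ± 1.18 to 150.3 ± 44.7 CPM, and Il9 from 2 reads over both WT libraries to 149 ± 18.4 CPM. Interferon response genes and p53 target genes also rose, with 19 of 26 and 15 of 19 members called. Glycolysis and hypoxia genes fell in 21 of 25 members. Across all 10873 genes tested, 1191 rose and 1089 fell. All these changes are relative to the early WT libraries that stood apart.

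Among the largest rises, Il9 had a ratio of KO to WT of 712 (95% counting interval 196 to 5869). Sprr1a, a cornified envelope precursor, rose by 8.33 ± 0.68 (adjusted p = 8.85e-05) and the calcium-binding protein gene S100a4 by 5.96 ± 0.39 (183 ± 26.5 against 2.93 ± 0.00131 CPM). S100a5 had no read in WT and was at least 32.9-fold higher in KO, against a floor of 3 counts over the group. Fcer1g, the signalling chain of Fc receptors, rose by 6.21 ± 0.67, Tnfsf4, which encodes OX40 ligand, by 5.86 ± 0.61, and the matrix metalloproteinase gene Mmp10 by 5.13 ± 0.69. The chemokine genes Ccl3 and Ccl17 rose as well, Ccl3 by 5.06 ± 0.98 and Ccl17 from 1 read over WT with a ratio of 66.8 (95% counting interval 11.9 to 2687). The serpin gene Serpina3g rose (229 ± 46.0 against 1.78 ± 1.93 CPM, adjusted p = 8.85e-05). Among the largest falls were complement C3 (-6.67 ± 0.42; 144 CPM in WT), the cytochrome P450 gene Cyp2s1 (-6.46 ± 0.39), the tyrosine kinase gene Matk (-6.72 ± 0.63) and Adm, which encodes the peptide hormone adrenomedullin (-5.86 ± 0.44). On the log2 scale Car11 fell by 7.46, the mucin gene Muc6 by 5.18 and H2-Q10 by 5.28, and Fam183b had 1.95 ± 1.82 against 123 ± 70.6 CPM. Stfa2 fell by 5.82 on the log2 scale and Stfa2l1 by 5.59, and both stay uncertain, as does Serpina3g, because these genes have near-identical copies that can share reads.

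The Th2 list had 10 of 28 members that rose and none that fell (11 and 0 adjusted over the list alone; camera adjusted p = 3.33e-08). Besides Il13 (4.48 ± 0.28, adjusted p = 2.1e-05) and Il9, these included Penk, the precursor of enkephalin peptides (3.74 ± 0.21; 718 ± 95.3 against 53.5 ± 8.72 CPM), Il10 (1.49 ± 0.16) and Il5 (3.13 ± 0.64, adjusted p = 0.00782). The Il5 call was lost in a fit of only the 4 libraries compared. Il4, with 39.5 ± 10.7 against 32.7 ± 9.17 CPM, was not called (0.27 ± 0.30, adjusted p = 0.553), and neither was Gata3 (0.37 ± 0.15). Of 20 cytotoxic and NK receptor genes, 10 rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 5.56e-05), among them Fcer1g, the granzyme genes Gzma (1.66 ± 0.19) and Gzmc (2.71 ± 0.50), and Serpinb9, an inhibitor of granzyme B (2.55 ± 0.50). Gzmb itself stood at 669 ± 82.3 against 648 ± 66.4 CPM and was not called (0.05 ± 0.15). Th1 genes rose in 6 and fell in 2 of 16 members (11 and 2 adjusted over the list alone; camera adjusted p = 0.00313, adjusted p = 0.0798 with an estimated correlation). The chemokine gene Ccl5 rose by 3.49 ± 0.33 and the IL-12 receptor gene Il12rb2 by 1.53 ± 0.26.

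Interferon response genes rose in 19 of 26 members and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 1.54e-10), with Mx1 at 4.56 ± 0.59, the nucleic acid sensor gene Zbp1 at 2.35 ± 0.31 and Xaf1 at 2.79 ± 0.42. All 15 called p53 targets rose (15 and 0 adjusted over the list alone; camera adjusted p = 2.2e-12), among them Mdm2, the ubiquitin ligase of p53 (1.73 ± 0.22), Zmat3 (2.30 ± 0.20), Ccng1 (1.88 ± 0.23) and Trp53inp1 (1.48 ± 0.16). The glycolysis and hypoxia list fell in 21 of 25 members (21 adjusted over the list alone; camera adjusted p = 5.45e-20, adjusted p = 0.123 with an estimated correlation). Its members included the glucose transporter gene Slc2a3 (-4.23 ± 0.29), Aldoc, which encodes aldolase C (-3.20 ± 0.22), and Pdk1, which encodes pyruvate dehydrogenase kinase (-2.02 ± 0.22). Cell cycle genes fell in 15 of 30 members (17 fell and 1 rose adjusted over the list alone; camera adjusted p = 7.85e-07), with a median of -0.79 that was 0.33 in limma on log2(RPKM + 1), which moved the median of all genes by 0.86 and also turned the sign of Mki67 and Top2a. Aurkb, a mitotic kinase gene, fell by 1.75 on the log2 scale. All these groups moved with the early WT libraries that stood apart. After the receptor read rate was subtracted from every count, 13 Th2, 10 cytotoxic, 7 Th1, 18 interferon and 15 p53 list members rose, and 21 glycolysis and 16 cell cycle members fell. In the same setting 1 Th2, 2 Th1 and 1 interferon member fell. In late against early WT, which uses the same early WT libraries, Th2 (15 rose and 3 fell of 28) and p53 genes (14 rose of 19) also rose. Glycolysis genes fell there in 22 of 25, while interferon (3 rose and 14 fell of 26) and cell cycle genes (9 rose and 2 fell of 30) went the other way. For the lists that moved alike, the deletion and a trait of the early WT libraries cannot be told apart.

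Lists whose camera test did not pass were Th17 (3 rose and 1 fell of 11), Treg (4 and 2 of 15), Tfh (1 and 0 of 13), CD8 lineage (1 and 1 of 5), naive and memory T cell (2 and 2 of 19), T cell receptor and identity (8 and 2 of 24), IL-2 and IL-4 receptor signalling (4 and 2 of 20) and ILC2 genes (2 and 1 of 11). Markers of other cells did not pass either: B cell (0 and 1 of 5), macrophage and dendritic cell (1 and 1 of 7), antigen presentation (2 and 2 of 9) and erythroid and neutrophil markers (1 and 1 of 5). Adjusted over the list alone, the counts that differed were 5 and 1 for Th17, 6 and 3 for naive and memory, 8 and 3 for T cell receptor, and 2 and 1 for erythroid and neutrophil genes. The only mast cell marker tested, Cpa3, rose by 4.30 ± 0.75. For the Treg, B cell and macrophage lists the median was positive and the test pointed down. Cd4 rose by 1.44 ± 0.18 and Cd3g by 0.91 ± 0.16, both components of T cell antigen recognition. Il22, listed with Th17 genes, had no read in WT and was at least 20.5-fold higher in KO. The count of called genes was 6895 in limma on log2(RPKM + 1), with 6565 rises and 330 falls. It was 1030 in a fit of only the 4 libraries compared, 3833 in a fit of all 16 libraries and 4517 with no filter on low values.

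Late cultures were compared in the same way to ask what Bcl11b controls once Th2 cells are established. In the late KO, 186 genes rose and 59 fell. The largest rise was in C5ar1, the receptor for complement fragment C5a, which had no read in WT, stood at 141 ± 3.11 CPM in KO and was at least 1324-fold higher. Chemokine genes Ccl5 and Ccl9, the NK receptor gene Cd244, the class II invariant chain gene Cd74 and Penk also rose. Gzmb, the gene of the cytotoxic protease granzyme B, fell from 3755 ± 74.7 to 1472 ± 4.53 CPM, and cell cycle genes fell together.

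Penk stood at 4777 ± 768 against 813 ± 108 CPM (2.55 ± 0.19, adjusted p = 0.000204). Ccl9 rose (391 ± 138 against 12.2 ± 2.61 CPM, adjusted p = 0.00122), Ccl5 by 3.92 ± 0.34 (adjusted p = 0.000478) and Cd244 by 6.40 ± 0.63 (adjusted p = 0.000882). Cd74 rose by 2.38 ± 0.25. Gzmb fell (-1.35 ± 0.15, adjusted p = 0.00185), as did the unconventional myosin gene Myo6 (-1.73 ± 0.15; 153 ± 4.24 against 507 ± 10.9 CPM). These 7 genes and C5ar1 were called whichever library was left out. Cd4 rose (3539.5 ± 338 against 1340.2 ± 73.3 CPM) and Sprr1a rose by 4.65 ± 0.58, calls lost without late WT replicate 1 (adjusted p = 0.0712 and 0.0784). Other large rises were AI836003 (4.94), Ppbp (5.16), Pdgfa (4.72), Ccl3 (4.46), Ccl4 (4.40), Tmem158 (4.25) and Cd63 (4.16). Other large falls were Scd1, a fatty acid desaturase gene (-1.60), Arhgap19 (-1.50), Spc24 (-1.41), Asns, which encodes asparagine synthetase (-1.39), Cdc25b (-1.37), Pdk1 (-1.30), Shcbp1 (-1.26) and Ccr2 (-1.26). Each of these other genes lost its call without 2 or more of the late libraries. The Th2 cytokine genes Il4, Il5 and Il13 were not called: Il4 stood at 126 ± 21.5 against 56.9 ± 7.54 CPM (adjusted p = 0.0787), Il5 at 1133 ± 207 against 345 ± 34.5 CPM (adjusted p = 0.120) and Il13 at 3162 ± 65.9 against 1889.9 ± 426 CPM (adjusted p = 0.128). Their means were higher in KO, so the missing calls do not show that they were unaffected. The main fit shares its spread with the early libraries. In a fit of only the 4 late libraries, 9 of 28 Th2 list members rose and 2 fell, against 3 and 0.

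Of 30 cell cycle genes, 12 fell and none rose, and 29 fell when adjusted over the list alone (camera adjusted p = 2.62e-35). Mki67 (-0.97 ± 0.13), Kif11 (-1.12 ± 0.17), Ccna2 (-1.09 ± 0.17) and Ccnb2 (-1.07 ± 0.17), genes of proliferation and mitosis, were among them. Cytotoxic and NK receptor genes rose in 4 and fell in 1 of 20 members (11 and 1 adjusted over the list alone; camera adjusted p = 7.89e-09), with Cd244, Fcer1g (3.40 ± 0.58) and Serpinb6b (1.91 ± 0.27) higher. Th1 genes rose in 4 of 16 members (4 adjusted over the list alone; camera adjusted p = 1.02e-07): Ccl3, Ccl4, Ccl5 and Lta (1.69 ± 0.30). Th2 genes rose in 3 of 28 (8 adjusted over the list alone; camera adjusted p = 2.04e-06): Penk, Il9 (2.24 ± 0.47) and Il1r2 (1.13 ± 0.25). p53 targets rose in 3 of 19 (5 adjusted over the list alone; camera adjusted p = 1.26e-06), with Mdm2 at 1.52 ± 0.22. Interferon response genes rose in 2 of 26 (3 adjusted over the list alone; camera adjusted p = 2.88e-05) and Treg genes in 2 of 15 (3 adjusted over the list alone; camera adjusted p = 0.000439), among them Tnfrsf9 at 1.30 ± 0.20. Apart from Penk, Ccl5 and Cd244, every called gene named here lost its call without 3 or more of the late libraries.

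Markers of antigen-presenting cells moved with these groups. B cell markers rose in 3 of 5 members (4 adjusted over the list alone; camera adjusted p = 2.61e-06), Cd79b standing at 8.63 ± 2.41 against 1.70 ± 0.466 CPM. Antigen presentation genes rose in 3 of 9 (5 adjusted over the list alone; camera adjusted p = 2.81e-07), with Cd74 at 132 ± 7.02 against 25.4 ± 4.81 CPM and H2-Aa at 35.5 ± 5.80 against 6.48 ± 0.841 CPM. The macrophage and dendritic cell list had 1 rise, Fcgr3 (3.14 ± 0.68), and 1 fall, Ccr2 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0181, adjusted p = 0.103 with an estimated correlation). After background subtraction, 0 B cell, 2 antigen presentation and 0 macrophage and dendritic cell genes rose. Cd79b (adjusted p up to 0.304), H2-Aa (0.267), Fcgr3 (0.423) and Ccr2 (0.234) lost their calls without any of the 4 late libraries. The Tfh list had 1 rise in 13 members, Pou2af1, a B cell coactivator gene (4 adjusted over the list alone; camera adjusted p = 0.000649, adjusted p = 0.103 with an estimated correlation). Of 25 glycolysis and hypoxia genes only Pdk1 fell (2 rose and 9 fell adjusted over the list alone; camera adjusted p = 1.78e-06, adjusted p = 0.270 with an estimated correlation). Naive and memory T cell genes (2 rose of 19) and T cell receptor genes (2 rose of 24) did not pass the camera test, nor did Th17 (0 of 11), CD8 lineage (0 of 5), IL-2 and IL-4 receptor signalling (0 of 20), erythroid and neutrophil (0 of 5) and ILC2 genes (0 of 11). The T cell receptor list had a median below 0 and a test pointing up, and the Th17 list the reverse. The single mast cell gene tested was not called. Adjusted over the list alone, the counts that differed were 3 and 2 for naive and memory, 0 and 1 for IL-2 and IL-4 receptor signalling, 2 and 0 for ILC2, and 1 and 0 for mast cell genes.

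The late Bcl11b counts rested on each late library: 30 genes were called without late KO replicate 1, 44 without late KO replicate 2, 20 without late WT replicate 1 and 28 without late WT replicate 2, against 470 and 467 without early WT replicate 1 or 2. Of the 51 named calls, 39, 34, 42 and 39 were lost without those 4 late libraries in that order, with adjusted p-values up to 0.434. DESeq2 called 587 genes, of which 64.9% rose against 75.9%, and a fit of only the 4 late libraries called 1816 (1058 rose and 758 fell), including all 245. limma on log2(RPKM + 1) moved the all-gene median by -0.16.

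The Bcl11b effect differed between stages for 339 genes, of which 199 had a higher and 140 a lower late effect. C3 fell early and rose late, a difference of 9.01 ± 0.54 (adjusted p = 7.86e-05). The late C3 level was 24.4 CPM in KO and 4.84 CPM in WT, and the late call of C3 was lost in 3 of the fits without 1 library. Il13 had a smaller effect late, with 4.48 early and 0.74 late and a difference of -3.74 ± 0.36 (adjusted p = 0.00177). The basement membrane gene Nid1 (7.88 ± 0.77), Slc2a3 (4.29 ± 0.37), the mucin gene Muc5b and Xist, the RNA of X inactivation, were the other genes with the smallest p-values. Muc5b had 3 reads in late WT and Xist 2 in early KO, so no fitted difference is given for them. The Xist call was lost after background subtraction. Of the genes called early, 110 rose and 46 fell at both stages, against 20.4 and 5.91 for independent lists. Some genes had almost no read in any late library, and 369 genes were called among those with a read in every late library. limma on log2(RPKM + 1) called 6108, of which 258 were higher late, with an all-gene median shift of -1.04. Without a late library the count was 66 (KO replicate 1), 49 (KO replicate 2), 38 (WT replicate 1) or 61 (WT replicate 2), and without early WT replicate 2 it was 704. DESeq2 called 902 genes, a fit of all 16 libraries 1283, a fit with no filter 1006 and background-subtracted counts 218.

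Late WT cultures of the Bcl11b experiment were compared with early WT cultures. Log2(RPKM + 1) values of early and late WT libraries correlated at 0.715 to 0.770, against 0.989 to 0.996 in WT of the Gata3 experiment. The libraries of the stages also differ in background reads and in abundant genes with few late reads. Culture stage cannot be separated from such differences, so the changes below cannot be read as Th2 maturation alone. Of 28 Th2 genes 15 rose and 3 fell (17 and 4 adjusted over the list alone; camera adjusted p = 2.75e-08, adjusted p = 0.0885 with an estimated correlation). Il13 rose from 6.70 ± 1.18 to 1889.9 ± 426 CPM (8.14 ± 0.32, adjusted p = 4.69e-08), and the epidermal growth factor receptor ligand gene Areg rose from 2 reads to 106 ± 4.06 CPM, a ratio of 506 (95% counting interval 139.8 to 4176). The neutrophil chemokine gene Cxcl3 had no early read and was at least 131-fold higher late. The protease gene Bace2 (7.04 ± 0.38) and Phlda1 (6.72 ± 0.44) also rose, as did Ccl17 from 1 read with a ratio of 146 (95% counting interval 26.2 to 5802). In all, 2140 genes rose and 2387 fell. p53 targets rose in 14 of 19 (14 adjusted over the list alone; camera adjusted p = 6.51e-05, adjusted p = 0.151 with an estimated correlation). Glycolysis and hypoxia genes fell in 22 of 25 (22 adjusted over the list alone; camera adjusted p = 4.77e-20, adjusted p = 0.141 with an estimated correlation), and B cell markers in 5 of 5 (5 adjusted over the list alone; camera adjusted p = 0.000162, adjusted p = 0.0927 with an estimated correlation). Among the glycolysis genes that fell, Gapdh (RPKM 81.2 and 70.1 in early WT, 2.32 and 2.77 in late WT) and Pgam1 (74.0 and 78.3, 1.58 and 1.96) belong to a group of abundant genes with few reads in every late library of this experiment. Their falls are uncertain, and the list was not tested without them. Naive and memory T cell genes fell in 12 of 19 (12 adjusted over the list alone; camera adjusted p = 7.26e-05, adjusted p = 0.0885 with an estimated correlation), with a median of -1.31 that was 0.14 in limma on log2(RPKM + 1), which moved the median of all genes by 1.04. The largest falls were in genes with almost no late read: D14Ertd449e, Dynlt1c, Dynlt1e, Dynlt1f and Gstp2 had 0 reads in all 4 late libraries, and Rn4.5s had 1 read in late WT. They are at least 1168-, 556-, 619-, 619- and 587-fold lower, and Rn4.5s has a ratio of late to early of 0.000127 (95% counting interval 3.26e-06 to 0.000718). By a pseudogene named after the gene or counts identical to another gene, Dynlt1e, Dynlt1f and Rn4.5s have a near copy. This measure found none for the other 3, which does not show that none exists, and all 6 falls are uncertain. Among genes with a read in every late library, 4329 were called. The comparison also moved with the early WT libraries that stood apart: limma on log2(RPKM + 1) called 7777 genes, and 2443 genes were called without late WT replicate 1.

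Early Gata3-deficient cultures were compared with WT to ask which genes depend on Gata3. The Th2 cytokine genes were lost: Il4 fell from 216 ± 22.8 to 2.66 ± 0.683 CPM, Il5 from 352 ± 57.8 to 3.28 ± 2.70 CPM and Il13 from 212 ± 2.83 to 1.71 ± 0.956 CPM. Ifng, the Th1 cytokine gene, stood at 961 ± 43.0 CPM in KO against 4.37 ± 2.45 CPM in WT, and Eomes, a transcription factor gene of cytotoxic cells, at 206 ± 2.15 against 0.798 ± 0.597 CPM. All 27 interferon response genes tested rose, as did 22 of 28 cytotoxic and NK receptor genes. Of 10601 genes tested, 1482 rose and 1776 fell.

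The largest rises included Fbln2, an extracellular matrix gene with no read in WT that was at least 241-fold higher in KO. Nov had 1 read over WT and a ratio of 1926 (95% counting interval 334 to 73614), and the NK receptor gene Klrb1c 1 read and a ratio of 641 (95% counting interval 119 to 26360.2). Pnliprp2, a lipase gene, and Mgl2, a lectin gene, had 1 read each in WT and ratios of 625 (95% counting interval 117 to 25786) and 595 (95% counting interval 103 to 22681). Apol7c rose by 8.22 ± 0.29. Clec2i, Ifi204, Serpina3h and Serpina3f rose, Clec2i with 1 read in WT and a ratio of 385 (95% counting interval 66.1 to 14648), Ifi204 with 2 and 363 (95% counting interval 99.9 to 2993), Serpina3h with 2 and 307 (95% counting interval 81.7 to 2449.8), and Serpina3f by 8.03 on the log2 scale. All 4 stay uncertain because they belong to families of near-identical genes. Among the largest falls, Akr1c18, a steroid dehydrogenase gene, fell from 3577 ± 230.5 to 15.4 ± 5.54 CPM (-7.86 ± 0.23, adjusted p = 4.67e-08). Areg (-7.56 ± 0.44), Il1rl1, which encodes the IL-33 receptor (-7.58 ± 0.45), the parathyroid hormone gene Pth (-7.56 ± 0.52) and the glutamate transporter gene Slc17a6 (-7.43 ± 0.27) fell too. Lhfpl1 had 2 reads in KO and a ratio of KO to WT of 0.00276 (95% counting interval 0.000334 to 0.01), Aldh3b2 1 read and a ratio of 0.00183 (95% counting interval 4.71e-05 to 0.0104), and Gap43 2 reads and a ratio of 0.00494 (95% counting interval 0.000601 to 0.0181). Tox2 had no read in KO and was at least 125-fold lower.

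Th2 genes fell in 21 of 26 members and rose in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 8.87e-34). Besides the cytokines (-6.33 ± 0.33 for Il4, -6.72 ± 0.46 for Il5 and -6.93 ± 0.23 for Il13), the chemokine receptor gene Ccr8 (-7.04 ± 0.26), Penk (-7.14 ± 0.24) and Il10 (-3.54 ± 0.19) fell. Th1 genes rose in 16 and fell in 2 of 20 members (17 and 2 adjusted over the list alone; camera adjusted p = 5.91e-12), with Eomes at 8.01 ± 0.32, Fasl at 6.60 ± 0.24 and Il12rb2 at 5.14 ± 0.29. Ifng rose by 7.79 ± 1.19 (adjusted p = 0.00488), a call lost without early WT replicate 1 (adjusted p = 0.0663) or 2 (0.0752). Tbx21, the gene of the Th1 factor T-bet, stood at 55.8 ± 7.61 against 11.2 ± 5.17 CPM and its call (2.30 ± 0.66, adjusted p = 0.0428) was lost without any of the 4 early libraries or either late WT library (adjusted p up to 0.229). Cytotoxic and NK receptor genes rose in 22 and fell in 2 of 28 members (24 and 2 adjusted over the list alone; camera adjusted p = 1.75e-27), including Fasl, Serpinb9 (6.21 ± 0.32), Cd160 (5.88 ± 0.35) and the cathepsin gene Ctsw (3.65 ± 0.20). Gzmb, at 13542 ± 3106 against 9088 ± 2541 CPM, was not called (0.58 ± 0.31). Interferon response genes rose in all 27 members (27 adjusted over the list alone; camera adjusted p = 6.44e-39), with Oas1a at 6.89 ± 0.31, Rtp4 at 5.79 ± 0.24, Oas3 at 3.90 ± 0.16 and Zbp1 at 2.45 ± 0.14.

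CD8 lineage genes rose in 4 and fell in 1 of 5 members (4 and 1 adjusted over the list alone; camera adjusted p = 0.000118, adjusted p = 0.0670 with an estimated correlation), with Cd8a at 3.52 ± 0.36, Runx3 at 1.13 ± 0.17 and the integrin gene Itgae at -2.95 ± 0.41. Treg genes fell in 10 and rose in 3 of 15 (12 and 3 adjusted over the list alone; camera adjusted p = 0.000687, adjusted p = 0.0759 with an estimated correlation): Ctla4 fell (-2.20 ± 0.14), as did the IL-2 receptor gene Il2ra (-2.20 ± 0.10), and Lrrc32 rose (4.57 ± 0.26). Th17 genes fell in 7 and rose in 3 of 11 (7 and 3 adjusted over the list alone; camera adjusted p = 0.00506, adjusted p = 0.0873 with an estimated correlation), with Il21 at -5.52 ± 0.35, Ahr, the aryl hydrocarbon receptor gene, at -3.23 ± 0.20 and Tmem176b at 2.24 ± 0.18. Tfh genes fell in 7 and rose in 1 of 11 (7 and 1 adjusted over the list alone; camera adjusted p = 0.000687, adjusted p = 0.222 with an estimated correlation), Icos at -2.04 ± 0.15. ILC2 genes fell in 7 and rose in 1 of 10 (7 and 1 adjusted over the list alone; camera adjusted p = 6.65e-06, adjusted p = 0.147 with an estimated correlation).

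Lists without a passing camera test were naive and memory T cell genes (6 rose and 7 fell of 19), T cell receptor genes (6 and 4 of 23), IL-2 and IL-4 receptor signalling (5 and 6 of 19), p53 targets (4 and 5 of 19), cell cycle (5 and 1 of 30), glycolysis and hypoxia (0 and 3 of 24), macrophage and dendritic cell (1 and 2 of 5), antigen presentation (3 and 0 of 6) and erythroid and neutrophil genes (0 and 0 of 4). Adjusted over the list alone, the counts that differed were 8 and 8 for naive and memory, 8 and 4 for T cell receptor, 4 and 6 for p53, 3 and 1 for cell cycle, and 0 and 2 for erythroid and neutrophil genes. Naive T cell genes went both ways: the kinase gene Txk rose by 4.26 ± 0.29 and S1pr1, the receptor for egress from lymph nodes, fell (-3.48 ± 0.16). The naive list had a median below 0 and a test pointing up, and the IL-2 and IL-4 list the reverse. No B cell marker passed the filter, and 1 mast cell gene was tested, the chymase gene Cma1, with 1 read in WT and a ratio of 94.0 (95% counting interval 17.3 to 3915). The fit of all 16 libraries called 1927 genes against 3258, 1573 had an absolute log2 fold change of at least 1, and 2093 were called without early KO replicate 2.

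Late Gata3-deficient cultures were compared with late WT to ask which genes depend on Gata3 at the stage labelled late. Il5 and Il13 stayed low in the late KO, Il5 at 2.43 ± 0.714 against 363 ± 104 CPM and Il13 at 5.48 ± 0.559 against 193 ± 17.9 CPM. Il4 stood at 126 ± 41.3 against 216 ± 50.9 CPM and was not called (adjusted p = 0.0551). Interferon response and Th1 genes were higher, and 899 genes rose and 604 fell.

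Il5 fell by 7.29 on the log2 scale (adjusted p = 0.000114), Il13 by 5.11 (adjusted p = 8.28e-07) and Il1rl1 by 4.79. Akr1c18 fell (-5.58 ± 0.21; 81.5 ± 4.00 against 3918 ± 99.2 CPM), as did Myo6 (-5.47 ± 0.42), the amino acid transporter gene Slc7a8 (-5.81 ± 0.30), Aldh3b2 (-5.42 ± 0.53) and the sialyltransferase gene St3gal6 (-5.12 ± 0.24). Lhfpl1 had 3 reads in KO and a ratio of 0.00535 (95% counting interval 0.000894 to 0.0127), and Tox2 3 reads and a ratio of 0.00846 (95% counting interval 0.00230 to 0.0330). Among the largest rises, the collagenase gene Mmp13 had 2 reads in WT and a ratio of 302 (95% counting interval 76.7 to 2309), Xdh, which encodes xanthine dehydrogenase, rose by 6.17 ± 0.60, the gelatinase gene Mmp9 from 2.00 to 98.3 CPM and the transcription factor gene Batf3 by 5.31 ± 0.31. Il12rb2 rose by 4.38 ± 0.28, Lrrc32 by 3.81 ± 0.26 and Tmem176b by 3.60 ± 0.18. C3 rose by 4.23 ± 0.72, a call lost without late WT replicate 1 (adjusted p = 0.0600) or 2 (0.0910). Serpina3f (4.62) and Serpina3g (3.91) have near-identical copies and stay uncertain, and their calls too were lost without late WT replicate 1 (adjusted p = 0.140 and 0.0886) or 2 (0.150 and 0.0732).

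Th2 genes fell in 11 and rose in 1 of 26 members (14 and 1 adjusted over the list alone; camera adjusted p = 1.86e-25), among them Ccr8 (-4.10 ± 0.21), Penk (-4.01 ± 0.20) and Epas1 (-1.61 ± 0.13). Th1 genes rose in 10 and fell in 1 of 20 (14 and 1 adjusted over the list alone; camera adjusted p = 3.8e-11), with Il12rb2, the IL-18 receptor gene Il18r1 (2.67 ± 0.29) and Eomes (3.48 ± 0.40) higher. Ifng stood at 45.8 ± 54.8 against 3.61 ± 0.659 CPM (adjusted p = 0.0952) and Tbx21 at 51.1 ± 38.5 against 12.5 ± 6.35 CPM (adjusted p = 0.0931), neither called. Interferon response genes rose in 18 and fell in 1 of 27 (21 and 1 adjusted over the list alone; camera adjusted p = 5.35e-17), among them Oas3 (2.38 ± 0.15), Rtp4 (2.88 ± 0.23), Gbp2 (2.54 ± 0.28) and Zbp1 (1.47 ± 0.13). Cytotoxic and NK receptor genes rose in 12 and fell in 2 of 28 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.50 with an estimated correlation), with Fasl at 2.03 ± 0.24 and Gzmc at 2.45 ± 0.29, and Gzmb, at 7307 ± 2202 against 9751 ± 2539 CPM, not called. ILC2 genes fell in 5 and rose in 1 of 10 (5 and 1 adjusted over the list alone; camera adjusted p = 8.22e-05, adjusted p = 0.336 with an estimated correlation), Areg at -4.14 ± 0.33.

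Th17 genes rose in 4 and fell in 2 of 11 (4 and 2 adjusted over the list alone; camera adjusted p = 0.00507, adjusted p = 0.136 with an estimated correlation), with Tmem176a at 3.48 ± 0.25 and Ahr at -1.77 ± 0.18. CD8 lineage genes rose in 2 and fell in 1 of 5 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0443, adjusted p = 0.340 with an estimated correlation). Glycolysis and hypoxia genes rose in 2 of 24 (2 adjusted over the list alone; camera adjusted p = 0.0443, adjusted p = 0.700 with an estimated correlation), with the hexokinase gene Hk2 at 1.22 ± 0.14. Lists that did not pass were Treg (2 rose and 2 fell of 15; median below 0, test pointing up), Tfh (4 and 2 of 11), naive and memory T cell (5 and 1 of 19), T cell receptor (5 and 2 of 23), IL-2 and IL-4 receptor signalling (7 and 4 of 19), p53 (3 and 2 of 19), cell cycle (0 and 1 of 30), macrophage and dendritic cell (2 and 1 of 5), antigen presentation (3 and 1 of 6) and erythroid and neutrophil genes (0 and 0 of 4). Adjusted over the list alone, the counts that differed were 2 and 3 for Treg, 5 and 2 for Tfh, 6 and 1 for naive and memory, 9 and 4 for T cell receptor, 9 and 4 for IL-2 and IL-4 receptor signalling, 3 and 3 for p53, and 0 and 0 for cell cycle genes. The 1 mast cell gene tested was not called, and no B cell marker was tested. The count was 722 at an absolute log2 fold change of at least 1, 701 in the fit of all 16 libraries, 905 without late WT replicate 1 and 839 without late WT replicate 2.

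**Figure D3:**
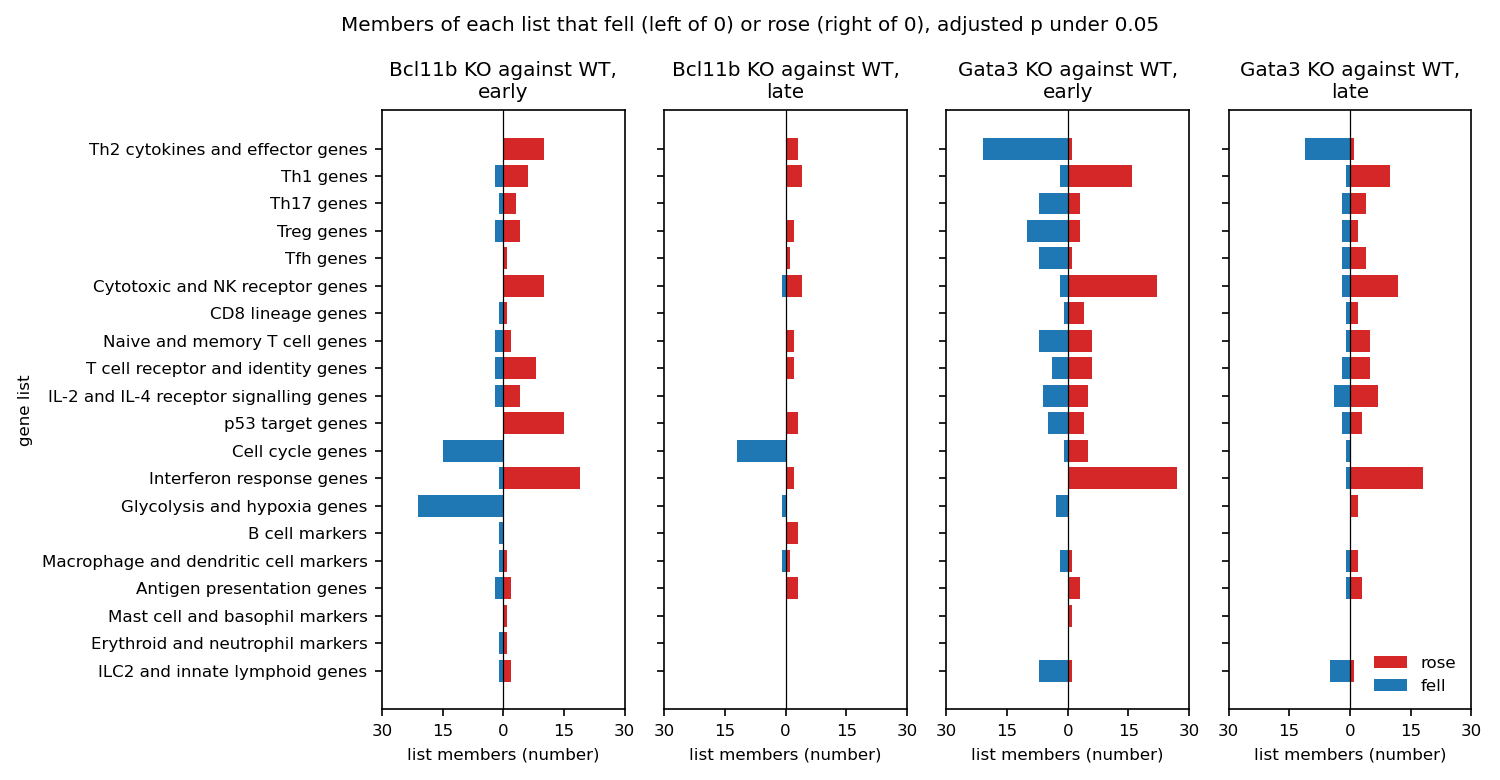
Number of members of each of the 20 gene lists that rose (red, right of 0) or fell (blue, left of 0) in each KO against WT comparison, at an adjusted p under 0.05. Interferon response genes rose in 19, 2, 27 and 18 members from left to right, and Th2 genes rose in 10 and 3 members without Bcl11b and fell in 21 and 11 without Gata3; the cell cycle median in the early Bcl11b panel flips from -0.79 to 0.33 under limma on log2(RPKM + 1), which moves all genes by 0.86.

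The Gata3 effect differed between stages for 1296 genes, with a higher late effect for 813 and a lower one for 483. The 6 smallest p-values all belonged to genes that fell early: Inhba, a subunit gene of activin (6.68 ± 0.22, adjusted p = 2.42e-07), Serpinf1 (5.18 ± 0.24), Mgll, which encodes monoacylglycerol lipase (3.87 ± 0.18), the kinesin gene Kif3a (3.92 ± 0.19), Timd2 (6.56 ± 0.37) and Ermn (5.78 ± 0.33). Ermn was at 156 CPM in early WT and 2.82 CPM in early KO, and at 161 CPM in late WT and 162 CPM in late KO. Gata3 itself had a difference of 1.14 ± 0.15 (adjusted p = 0.00111). At both stages 546 genes rose and 440 fell, against 126 and 101 for independent lists. The fold changes of the stages correlated across genes at r = 0.61, though genes are not independent replicates, and over all genes the SD of the log2 fold changes was 1.36 early and 0.77 late (up to 0.85 without a late library). Late changes of genes called early were 0.363 times the early ones, a slope that choosing genes on the early test lowers. Early changes of genes called late, where the choice favours the late ones, were 1.18 times the late ones (0.989 to 1.19 without a late library). The share of differences that were higher late, 62.7%, was 47.5% in limma on log2(RPKM + 1), and the count was 603 in the fit of all 16 libraries, 792 without early KO replicate 1 and 705 without early KO replicate 2.

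Late and early WT cultures of the Gata3 experiment gave no called gene in edgeR, with 126 genes at an unadjusted p under 0.05. Of the gene lists, glycolysis and hypoxia genes were lower (camera adjusted p = 5.57e-06) and interferon response genes higher late (camera adjusted p = 0.0152), both with an adjusted p of 0.949 with an estimated correlation. DESeq2 called 0, with 69 at an unadjusted p under 0.05, limma on log2(RPKM + 1) called 0, with 149, and limma on log2(RPKM + 0.1) called 1, with 167. That gene, the small nucleolar RNA Snord99, was chosen after its values were seen and stood at 0 CPM early and 0.316 CPM late. The smallest p-values belonged to the interferon-inducible GTPase genes Gbp10 (0.61 ± 0.14), Gbp4 (0.48 ± 0.12), Tgtp1 (0.64 ± 0.17) and Tgtp2 (0.65 ± 0.16) and to Prickle1 (2.02 ± 0.50) on the higher side, and to Bcl3 (-0.42 ± 0.13), Eid2 (-1.51 ± 0.42), Endog (-0.48 ± 0.15), Mink1 (-0.41 ± 0.13) and Pgrmc2 (-0.79 ± 0.23) on the lower side, none of them called. WT libraries with the same replicate number were closer between stages than replicates within a stage: the median excess over counting noise was 2.78 for replicate 1 and 2.00 for replicate 2, against 5.22 between the early and 4.94 between the late replicates.

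The effects of losing Bcl11b and Gata3 were compared to ask which genes they share. Early, 823 of 9986 genes were called in both experiments: 255 rose in both, 189 fell in both, 270 rose without Bcl11b and fell without Gata3, and 109 did the reverse. Independent lists would give 146, 152, 192 and 115. Fcer1g, Serpina3g, C2cd4b, Smpdl3b (4.79 and 4.68 without Bcl11b and Gata3), the interferon-inducible gene Ifit1 (4.44 and 4.01) and the chemokine gene Ccl1 rose in both. Aldh3b2, Fam69c, Foxb1, Gpr15, Stfa1 and Stfa2 fell in both. Il13 (4.48 and -6.93), Areg, Cxcl3, Mmp10, Pth (4.59 and -7.56) and Syn2 (4.11 and -3.98) rose without Bcl11b and fell without Gata3. C3 (-6.67 and 3.53), Ube2l6, Tspan9 (-3.38 and 5.63), Cd93 (-3.36 and 3.13), Emilin2 (-3.56 and 2.92) and Haao (-3.85 and 2.85) did the reverse. Genes named here without values, apart from Serpina3g, had 3 reads or fewer in a group of at least 1 experiment. Of these 24 genes, 17 kept both calls whichever library was left out. Of the shared genes 53.9% moved the same way (Fisher's exact test, odds ratio 1.64, p = 0.001004), and p was 0.0819 for the limma calls on log2(RPKM + 1).

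Late, 63 genes were called in both: 39 rose in both, 5 fell in both, 18 rose without Bcl11b and fell without Gata3, and 1 did the reverse, against 11.3, 3.41, 8.35 and 4.62 for independent lists. Xdh (2.75 and 6.17), Mndal (2.67 and 3.61), Rsad2 (3.09 and 3.23), Serpina3g (2.51 and 3.91), the glucose transporter gene Slc2a6 (2.48 and 2.38) and C3 (2.34 and 4.23) rose in both. Myo6 (-1.73 and -5.47), Psat1 (-0.86 and -0.78), Afg3l2 (-0.82 and -0.85), Smc5 (-0.84 and -0.68) and Exosc8 fell in both. Penk (2.55 and -4.01), the cytokine receptor gene Csf2rb2 (2.22 and -2.72), Furin (2.32 and -2.20), Ctsh, Lat2 (2.21 and -2.04) and Pacsin1 (2.81 and -1.88) rose without Bcl11b and fell without Gata3, and Aak1 (-1.15 and 0.52) did the reverse. Ctsh had no read in Gata3 KO. Of these 18 genes only Myo6 and Penk kept both calls whichever library was left out, and 10 kept the Gata3 call. Rsad2 and Serpina3g lost the Bcl11b call without any of the 4 late libraries (adjusted p up to 0.276 and 0.242), and the Gata3 call without 2 libraries each (up to 0.113 and 0.0886). The same direction held for 69.8% (Fisher's exact test, odds ratio 10.8, p = 0.0213). The test did not pass at an absolute log2 fold change of at least 1 (Fisher's exact p = 0.34) or for limma calls on log2(RPKM + 0.1) (p = 0.15), or without Bcl11b late KO replicate 1 or 2 (p = 0.333 and 0.389), Bcl11b late WT replicate 1 or 2 (0.375 and 0.333), Gata3 late KO replicate 2 (0.185) or Gata3 late WT replicate 1 (0.144). Across genes, fold changes correlated at r = 0.15 early and 0.17 late (Spearman 0.05 and 0.21), with genes not independent replicates.

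Binding was mapped to ask where Bcl11b and GATA3 meet on chromatin in late WT Th2 cells. After peaks overlapping the input peaks were left out, 15262 Bcl11b and 27199 GATA3 peaks were used. Of the Bcl11b peaks, 6642 (43.5%, 95% Wilson interval 42.7 to 44.3) overlapped a GATA3 peak by at least 1 bp, and 7022 GATA3 peaks (25.8%) overlapped a Bcl11b peak. When the GATA3 peaks were shifted along the chromosomes 100 times, the median overlap was 1.53% and the highest 1.83%. These shifts do not account for regions in which peaks of any factor may gather. Within 1 kb of a transcription start lay 28.3% of Bcl11b peaks and 9.29% of GATA3 peaks. Bcl11b peaks shared with GATA3 were there less often (17.3%) than those without GATA3 (36.8%).

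In mm10 coordinates, as the files give them, the strongest Bcl11b peak by fold enrichment lay at chromosome 18, 75599659 to 75600473, downstream of Gm10532 (25.6-fold), followed by chromosome 19, 42011579 to 42013161, upstream of Ankrd2 (21.1-fold) and chromosome 12, 33409972 to 33410749, downstream of Efcab10 (20.7-fold). The strongest GATA3 peaks lay at chromosome 11, 53344905 to 53345957, upstream of Aff4 (42.0-fold), chromosome 18, 89486248 to 89487452, in Dok6 (41.3-fold) and chromosome X, 157259048 to 157260293, in Phex (39.9-fold). At the Th2 cytokine cluster on chromosome 11, which holds Il4 (53612460 to 53618665), Il13 (53631323 to 53634702), Rad50 (53649519 to 53707319) and Il5 (53720794 to 53725103), both factors had peaks. Il4 had 13 GATA3 and 3 Bcl11b peaks, Il13 had 9 and 7, and Il5 had 3 and 3, each peak counted for the gene with the closest start. Rad50 was closest for 3 GATA3 peaks and no Bcl11b peak, but peaks counted for Il13 lie inside Rad50, among them a GATA3 peak at 53654591 to 53655632 (10.7-fold) and a Bcl11b peak at 53654414 to 53655694 (4.22-fold). The strongest GATA3 peak of the cluster (25.4-fold) lay 1254 bp upstream of Il13, at 53635175 to 53636736, over a Bcl11b peak at 53635870 to 53636703 (4.27-fold). In Il4, the GATA3 peak at 53617095 to 53618505 (11.1-fold) overlapped the Bcl11b peak at 53616408 to 53618284 (3.22-fold). Bcl11b (chromosome 12, 107910403 to 108004145) had 6 Bcl11b and 15 GATA3 peaks. Gata3 (chromosome 2, 9857078 to 9887953) had 22 and 38, Ifng had 1 and 4, Tbx21 2 and 3, and Gzmb 3 and 4. These counts include distant peaks: for Gata3 the farthest Bcl11b and GATA3 peaks lay 313867 and 313882 bp from the transcription start. For Ifng the Bcl11b peak lay 36501 bp and the GATA3 peaks 21781 to 40580 bp from the start, all outside the gene. Each antibody had 1 library, so peak differences have no replicate check.

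**Figure D4:**
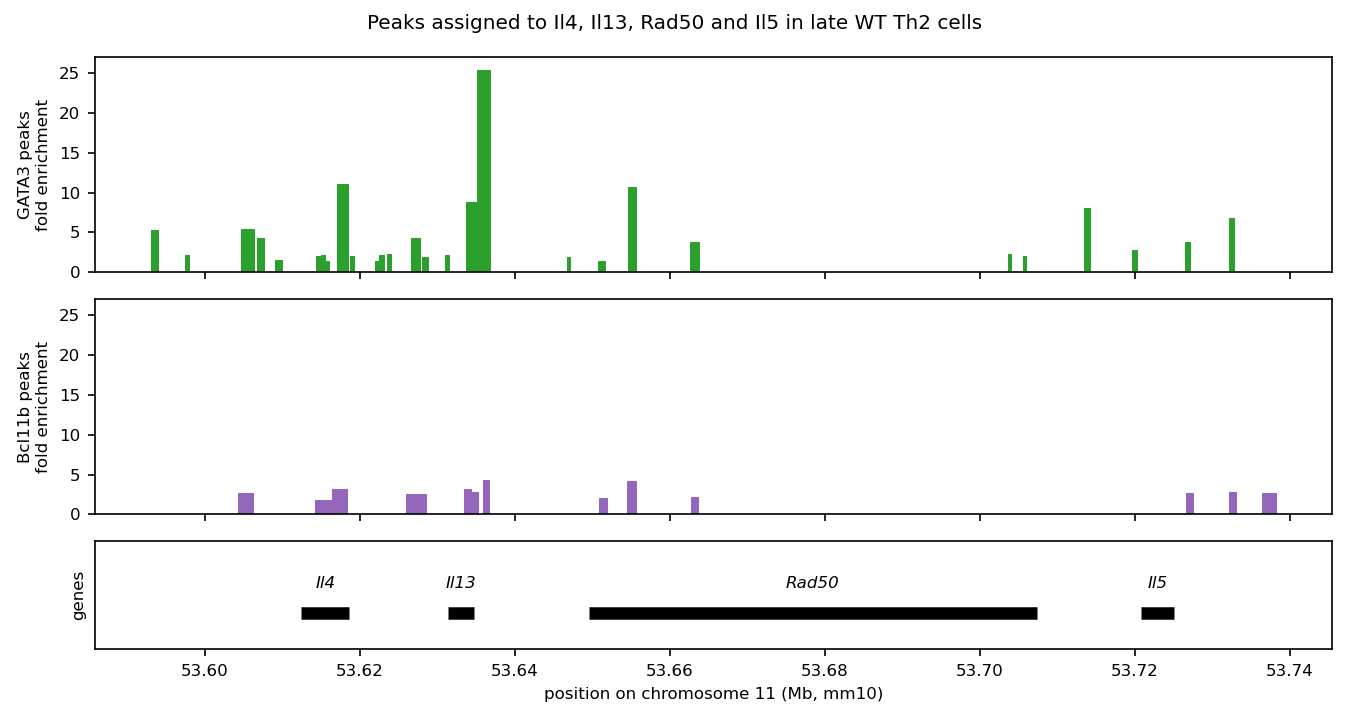
Fold enrichment of GATA3 peaks (top) and Bcl11b peaks (middle) assigned to Il4, Il13, Rad50 and Il5 along chromosome 11 in mm10, with the genes below. The strongest GATA3 peak (25.4-fold) lies 1254 bp upstream of Il13, where a Bcl11b peak reaches 4.27-fold.

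Genes that changed in the late KO were then compared with genes that had an assigned peak. GATA3 peaks were assigned to 1057 of the 1503 genes changed without Gata3 (70.3%) against 50.3% of the other tested genes (Fisher's exact test, odds ratio 2.34, p = 3.684e-48). They were assigned to 76.2% of genes that fell and 66.4% of genes that rose, an order that turned without late KO replicate 2 (68.5% and 71.4%). In a logistic regression with expression level and gene length, the odds ratio was 2.08 (95% interval 1.84 to 2.36). Bcl11b peaks were assigned to 143 of the 245 genes changed without Bcl11b (58.4%) against 49.8% of the others (odds ratio 1.41, Fisher's exact p = 0.00961). Among the 1816 calls of a fit of only the 4 late libraries, a setting chosen after the values were seen, it was 1.37 (Fisher's exact p = 1.056e-09). Without 1 of the early libraries it was 1.30 to 1.52. With expression level and gene length in the model the Bcl11b odds ratio was 1.14 (95% interval 0.873 to 1.49). By Fisher's exact test it was 1.27 (p = 0.113) for genes with an absolute log2 fold change of at least 1, and 1.00 without late KO replicate 1 or 2, 1.22 without late WT replicate 1 and 1.55 without late WT replicate 2, none of these 4 passing the test.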

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

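The tests of undeleted cells and of depth in the late Gata3 KO libraries were chosen only after the result was seen.

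The effect of Bcl11b loss differed between stages for 339 genes. The late effect minus the early one was 9.01 for C3, -3.74 for Il13, 7.88 for Nid1 and 4.29 for Slc2a3 on the log2 scale. The fitted values for Muc5b (11.20) and Xist (8.08) rest on groups of 3 reads (late WT) and 2 reads (early KO) and are not sizes of an effect. Early WT, whose libraries had the most reads over sensory receptor transcripts, had 19 and 28 Xist reads, and the Xist call was lost after background subtraction. The effect of Gata3 loss differed between stages for 1296 genes. It was higher late by 5.78 for Ermn, 6.68 for Inhba, 3.92 for Kif3a, 3.87 for Mgll, 5.18 for Serpinf1 and 6.56 for Timd2 on the log2 scale.

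The smaller Gata3 effect in late cultures was weighed against technical causes. If undeleted cells in the late KO libraries were the whole difference, all genes lost early would sit at a like share of WT, yet 25.7% of 70 such genes had under 0.25 times the median share. Il5 stood at 0.67% of its WT level, Il13 at 2.84%, Gata3 at 75.5% and Il4 at 58.4%, so a single share of undeleted cells does not account for the pattern. Low depth of late KO replicate 1 was tested by leaving it out: the slope of late on early fold changes over all genes was 0.379. It was 0.344 with all libraries and 0.291 without late KO replicate 2. Low depth adds spread to the late fold changes but would not by itself lower this slope, so the slope cannot decide on depth. A stage-specific dependence on Gata3 remains a hypothesis. Slow loss of stable transcripts, and undeleted cells as a part of the difference, were not tested. Gata3 itself stood at 34.3% of its WT level in early KO, against 75.5% late. The culture of this experiment is not given, and its late and early WT gave no called gene.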

How the results depend on the processing

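The tests with background-subtracted counts, the longest transcript per gene, genes with a read in every late library and bound genes from a fit of 4 libraries were chosen only after the result was seen. For the named genes, 5596 results of alternatives kept the main result, 418 were weaker, 34 stronger, 12 reversed and 9 moved. The quantile normalization planned for RPKM tests was not run, since counts were tested. The RPKM totals bear on the limma settings of early Bcl11b KO, and the cause of the other differences below was not tested.

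Early Bcl11b KO (2280 genes): 3833 in the fit of all 16 libraries, 1030 with only the 4 compared, 6985 and 6895 in limma on log2(RPKM + 0.1) and log2(RPKM + 1), and 4517 with no filter. Both limma settings shifted all genes, by 1.14 and 0.86, and reversed Bcl11b (0.060 and 0.047), Foxo1 (0.58 and 0.55), Mki67 (0.18 and 0.18), Runx3 (0.35 and 0.33), Stat6 (0.44 and 0.40) and Top2a (0.0092 and 0.009). These settings use RPKM, whose library total held 20.7% and 16.9% gene reads in early WT against 40.7% and 42.7% in early KO. That difference raises RPKM in KO relative to WT for genes as a whole, so the reversals carry this shift. Late Bcl11b KO (245): 587 with DESeq2, 148 with background-subtracted counts, 701 with all 16 libraries, 1816 with only the 4 compared and 89 in limma on log2(RPKM + 0.1). Early Gata3 KO (3258): 1573 at an absolute log2 fold change of at least 1 and 1927 with all 16 libraries. Late Gata3 KO (1503): 722 at that fold change and 701 with all 16 libraries.

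Bcl11b stage difference (339): 902 with DESeq2, 218 with background-subtracted counts, 1283 with all 16 libraries, 5899 and 6108 in limma on log2(RPKM + 0.1) and log2(RPKM + 1), and 1006 with no filter. Gata3 stage difference (1296): 603 with all 16 libraries. Late against early WT gave 7770 and 7777 in these limma settings and 8016 with no filter in the Bcl11b experiment (4527), and 1 in limma on log2(RPKM + 0.1) in the Gata3 experiment (0).

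Leaving out 1 library at a time gave 1572 to 2511 genes for early and 20 to 470 for late Bcl11b KO, 2093 to 3459 for early and 839 to 1495 for late Gata3 KO, 38 to 704 and 705 to 1451 for the stage differences, and 2443 to 5078 and 0 for late against early WT.

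Shared direction of effects, early (53.9%): 53.6% (Fisher's exact p = 0.0819) for limma on log2(RPKM + 1), and 52.8% to 57.5% without a library. Late (69.8%): 68.4% at an absolute log2 fold change of at least 1, 70.6% in limma on log2(RPKM + 0.1), and 63.5% to 75% without a library. Peak overlap (43.5%): 36.0% for the peaks with the higher scores and 41.5% at 50% of the shorter peak. Bcl11b-bound genes (odds ratio 1.41): 1.37 with the calls of only the 4 libraries compared, 1.27 at that fold change, 1.14 in logistic regression, and 0.999815 to 1.55 without a library, with 0.999816 without late KO replicate 1 and 0.999815 without late KO replicate 2. GATA3-bound genes (2.34): 2.06 at that fold change, 2.08 in logistic regression, and 2.26 to 2.79 without a library. Lists past the threshold: early Bcl11b (7) 11 with fry and 4 with camera on log2(RPKM + 0.1), early Gata3 (9) 4 and late Gata3 (8) 3 with an estimated correlation.

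The libraries share only replicate numbers. With a replicate block, late Gata3 KO gave 2537 genes, the Gata3 stage difference 2385, the Bcl11b stage difference 204, and late shared direction 69.7% (Fisher's exact p = 0.0555). Deviations of libraries with the same number correlated at 0.22 to 0.66 in the Gata3 and -0.09 to 0.39 in the Bcl11b experiment.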

Other observations

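The tests of evenly spread background, of background as the source of the early calls, and of genes switched off in late cells were chosen only after the result was seen, while those of male DNA, of receptor transcription and of reads with several map positions were chosen before.

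The experiments differ in markers of sex. Ddx3y, a gene of the Y chromosome, had an RPKM of 1.54 to 13.2 over the Bcl11b libraries and at most 0.0235 over the Gata3 libraries, and Xist 0.00230 to 1.16 and 16.2 to 25.9.

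The early WT libraries of the Bcl11b experiment carry reads over genes of sensory neurons. Background spread evenly over the genome, for example from genomic DNA, could be the cause: at the receptor read rate it would supply 0.817 times the reads in excess. Unexpressed genes on chromosome X had 0.517 times the read rate of those on autosomes, the share of male DNA, which is consistent with genomic DNA. Transcription of the receptors would give other unexpressed genes a lower rate, but their rate was 1.24 times that of the receptors. After background subtraction 84.5% of the early Bcl11b calls remained, a share that pools rises and falls, while reads added in WT would appear as falls in KO. Among the 9986 genes tested in both experiments, 885 fell before and 878 after subtraction, and 1122 and 989 rose. The rate subtracted, that of the receptors, was below the rate of other unexpressed genes. Subtraction therefore cannot decide how far background shaped the early calls, and other differences of the early WT libraries were not tested.

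Some abundant genes, among them Ppia, Actg1, Rps29 and Gapdh, had far lower levels in the late Bcl11b libraries than in the early ones. Gapdh, a glycolysis gene, had an RPKM of 1.35 to 2.77 there. Reads with several map positions may have been left out of these libraries' counts: near copies were 5.86 times as frequent among the lost genes as among other abundant genes (28 of 47 against 111 of 1092, Fisher's exact p = 1.99e-15). In the Gata3 experiment their late to early WT ratio had a median of 0.927. This cannot decide whether they were switched off in the late Bcl11b cultures. Late and early WT of the Gata3 experiment gave no called gene, and the lost genes were chosen for a high level there. Other lost genes, Ppia and Actg1 among them, had no near copy by this measure, which misses copies with other names and unlike counts. Comparisons of late with early Bcl11b libraries are uncertain for all 47. Less abundant genes and genes that lost a smaller part of their reads were not examined, so the doubt may reach further.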
